A study of Mus musculus with 4 samples.

How the data were processed

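Total RNA sequencing was done on B cells purified by CD19 from the spleen of virgin adult female B6CASTF1/J mice, the first generation of a cross of a C57BL/6 mother with a CAST/EiJ father. The 4 libraries were biological replicates 1 to 4, each made from 300 ng of total RNA after depletion of ribosomal RNA, with a directional kit and with ERCC spike-in RNA added. Per the labels, replicates 1 and 2 came from mice of 62 days and replicates 3 and 4 from mice of 55 days. A free-text line of the labels gives 62 days for all 4 libraries, and the age field of each library was used here. The labels give no sequencing run, harvest date or litter.

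For each library the authors deposited a gene table, a transcript table of the same quantifier and a transcript table of another quantifier, all against assembly mm10 with the M21 annotation. The gene table and its transcript table hold expected counts (estimated reads, not whole numbers, not scaled), deposited beside TPM (relative transcript abundance, length-corrected, over genes and spike-ins). The other transcript table holds estimated counts and TPM, per the file headers, and these counts have the same unit as those of the gene table. The programs were not given in the sources used here. Other deposited columns, per the file headers, were the effective length and the posterior standard deviation of the count, the quantifier's own measure of how surely reads were assigned to a gene. In the gene tables the effective length was 0 for very short genes, so that TPM was void for them and mitochondrial transfer RNAs were listed at 0.

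The gene tables held 55536 annotated genes, 96 spike-ins, 1 phiX entry and 26248 entries with numeric identifiers. Every annotated gene was matched by identifier to the reference annotation, which supplied symbols, classes and positions. The numeric entries were left out of all comparisons because no file names them. The transcript table of the other quantifier was summed to genes, which gave 55450 genes in both. Total expected counts were 17516657, 18261129, 18403387 and 18791040 in replicates 1 to 4. At this depth a count of 0 allows up to 3 counts in a library. Reads carry no molecular identifiers, so counting limits and intervals cover counting error only.

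Descriptive values are means ± SD over the 4 libraries with no test. They comprise the TPM of marker lists, the summed TPM of markers of other cell types, immunoglobulin constant region shares, RNA class shares of counts, the spike-in share, and the number of genes at a TPM of at least 1 in every library. The 2 quantifiers were compared by Spearman correlation across genes within each library. They were also compared by genes at least 4-fold apart in the same direction in all 4 libraries with a mean TPM of at least 10 by either. To rank these genes by ratio, 0.1 TPM was added to both values.

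The 62-day and 55-day libraries were compared, 2 against 2, with the edgeR 4.0.16 quasi-likelihood test on rounded expected counts with TMM scaling in R 4.3.3. The default expression filter left 14127 genes, and the threshold was a Benjamini-Hochberg adjusted p of 0.05. The common biological coefficient of variation was 8.48%. CPM of single genes in this comparison used the TMM-scaled library sizes, and sums over genes that share reads used the plain library sizes. Of 44 gene lists, the 40 with at least 4 tested members went into camera (limma 3.58.1) with a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. No paired analysis was possible because the replicate numbers are not shared between the ages. Gene lists, tests, thresholds and the rule for named genes were set before the data were examined. The rule names, for the profile, the 20 nuclear genes of highest mean TPM and the 4 highest members of each list. For age it names up to 12 genes per direction past the threshold with a mean TPM of at least 1 and no overlap between ages, and up to 12 passing list members per direction. For the quantifiers it names the 10 genes of largest ratio in each direction.

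The tests were also tested on simulated data. With 200 of 14127 genes changed in simulated libraries of this size, the age test called 74.6% of genes changed 2-fold and 94% of those changed 4-fold, and 3.88% of calls were unchanged genes. With no gene changed it called 0 genes in 5 runs. The simulated genes were independent, shared no reads, varied only as usual for their level, and had no outlying library. These rates therefore do not cover errors from shared reads, from single genes of high spread or from an outlying library. The comparison of quantifiers found 200 of 200 genes set 8-fold apart and 0 others.

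Alternatives covered scaling by DESeq2 1.42.0 size factors, by library size and by spike-ins; the DESeq2 Wald test, limma-voom and limma on log2(TPM + 1) or log2(TPM + 0.1); no count filter and a mean count of at least 50; leaving out immunoglobulin or mitochondrial genes, or all but protein-coding genes; the other quantifier; an adjusted p of 0.10; and leaving out each replicate. For profile values they covered CPM (counts scaled by library size alone) in place of TPM, other thresholds and the other quantifier. One alternative was added after seeing the data, a test of the 13495 genes of low assignment uncertainty, whose mean posterior standard deviation was at most 10% of the mean count; its threshold is 0.1 as a fraction. For outlying libraries Dixon's ratio was compared with 0.829. Summaries and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.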

Results

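Total RNA was sequenced from CD19-purified splenic B cells of F1 hybrid female mice in 4 biological replicates, 2 from mice of 62 days and 2 from mice of 55 days. Total expected counts ranged from 17516657 to 18791040 per library. ERCC spike-ins took 0.286% ± 0.00915 (SD, n = 4) of counts. Log CPM of library pairs correlated across genes with Pearson coefficients of 0.985 to 0.988, where genes are not independent replicates. Replicate 4 stood apart from the others in chi-square per gene against counting error. This was 16.4 with replicate 1, 16.9 with replicate 2 and 18.15 with replicate 3, the other library of 55 days. The pairs among replicates 1 to 3 were at 5.45 to 7.77, with 5.72 for replicates 2 and 3 of different ages. Genes of high count that share reads weigh heavily in these values. In replicates 3 and 4 mt-Co2 held 2 and 29501 counts and its nuclear copy Gm28661 35997 and 255. How much of the distance of replicate 4 came from such splits was not tested. Pearson coefficients hardly set it apart, at 0.9848 with replicate 3 against 0.9851 for replicates 1 and 3. The labels state no hypothesis. The comparisons below describe the expression profile of the B cells, the differences between the ages, and the differences between the quantifiers.

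Genes of mature B cells were at high levels in every library. All 16 genes of the pan-B list were above 1 TPM in every library, and the list median was 270.5 ± 12.5 TPM (SD, n = 4). Cd79a and Cd79b, the signalling chains of the B cell receptor, were at 580 ± 24.7 and 465 ± 11.2 TPM. Cd37, a tetraspanin of B cells, was at 578 ± 20.2 TPM, and Cd19, the antigen used for purification, at 405 ± 15.3 TPM. The 8 follicular B cell genes had a median of 191.5 ± 21.1 TPM, with Klf2 at 1158 ± 88.6, Ccr7 at 276 ± 14.9 and Sell at 192 ± 20.6 TPM. The 11 marginal zone genes had a median of 34.6 ± 2.32 TPM, among them the complement receptor gene Cr2 at 276.5 ± 9.77, Plac8 at 145 ± 0.879, Notch2 at 92.1 ± 1.28 and Mzb1 at 83.8 ± 6.77 TPM.

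Lists of other B cell stages were lower. The plasma cell list had a median of 7.31 ± 0.936 TPM, led by Irf4 at 170 ± 17.3 and Jchain, the joining chain of secreted antibody, at 44.7 ± 6.58 TPM. The immature B cell list had a median of 0.996 ± 0.311 TPM. Its members Cd24a, at 223 ± 6.25 TPM, and Vpreb3, at 41.8 ± 4.37 TPM, stood well above Cd93, at 3.45 ± 0.230 TPM. The germinal centre list had a median of 0.755 ± 0.0797 TPM, led by Bcl6 at 23.7 ± 1.30 and Neil1 at 23.3 ± 2.01 TPM. The B1 list had a median of 0.71 ± 0.195 TPM, led by Bhlhe41 at 9.18 ± 1.32 TPM. The age-associated B cell list had a median of 5.76 ± 0.370 TPM, with Zeb2 at 27.7 ± 1.30 and Fcrl5 at 10.7 ± 0.696 TPM.

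**Figure D1:**
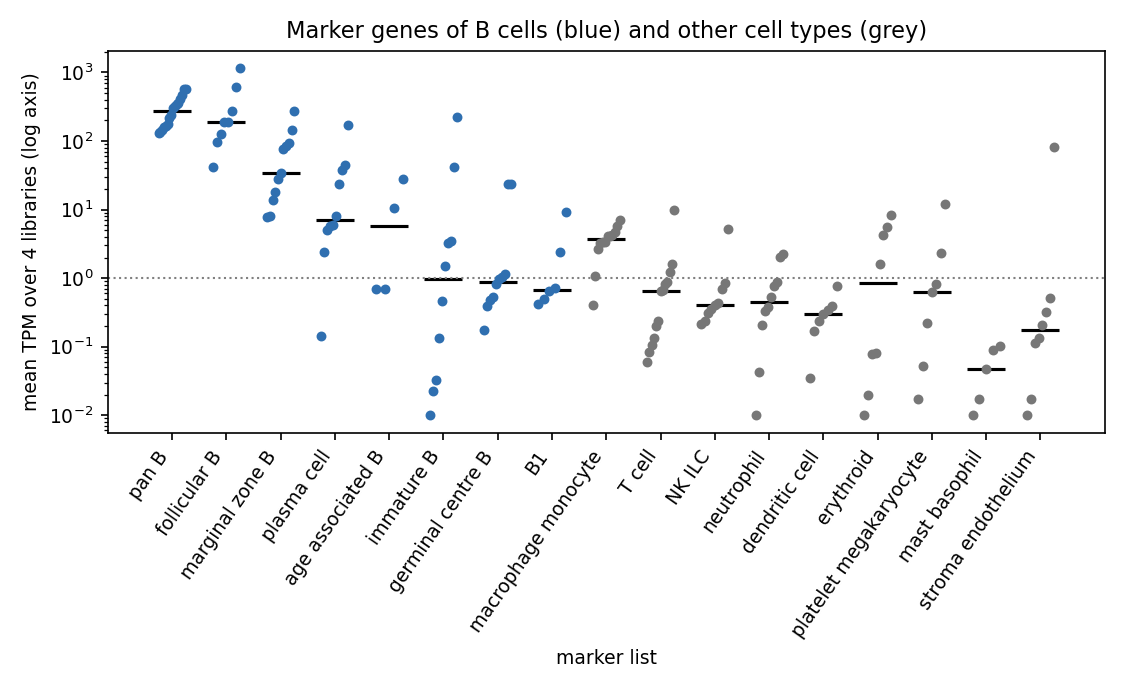
Mean TPM over the 4 libraries of each marker gene (points, log axis) by marker list, with the median of those gene means as a black bar. B cell lists are blue and other cell types grey, genes under 0.01 TPM are drawn at 0.01, and the dotted line marks 1 TPM. The pan-B genes all lie above 100 TPM, and most markers of other cell types lie near or below 1 TPM.

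Markers of other cell types were low. Summed over all non-B lists they reached 198 ± 15.2 TPM, or 4.18% ± 0.294 of the summed TPM of the pan-B genes. Pecam1, an adhesion molecule also found on leukocytes, made up 81.3 ± 3.83 TPM of this sum, the integrin gene Itgb3 11.9 ± 1.01 and the kinase gene Lck 9.80 ± 1.82 TPM. Without these 3 genes the sum was 95.0 ± 10.1 TPM. The macrophage and monocyte list had a median of 3.72 ± 1.07 TPM, with Csf1r at 5.77 ± 1.57 and C1qb at 4.63 ± 1.38 TPM. Medians were 0.405 ± 0.149 TPM for T cells, 0.395 ± 0.0451 for natural killer cells, 0.481 ± 0.130 for neutrophils, 0.26 ± 0.136 for dendritic cells, 0.855 ± 0.469 for erythroid cells, 0.518 ± 0.247 for megakaryocytes, 0.03 ± 0.0356 for mast cells and basophils, and 0.16 ± 0.0715 for stroma and endothelium. The T cell receptor complex gene Cd3e was at 1.24 ± 0.454 TPM and the haemoglobin gene Hba-a2 at 4.27 ± 2.10 TPM.

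Unswitched isotypes made up nearly all of the heavy chain RNA. Ighm accounted for 78.4% ± 1.57 (SD, n = 4) of heavy chain constant region TPM and Ighd for 20.3% ± 1.78. The IgG genes together accounted for 1.01% ± 0.171, most of it Ighg3 with 0.661% ± 0.153, and Igha for 0.261% ± 0.189. Among light chain constant regions Igkc, the kappa chain, took 59.3% ± 1.95 of TPM, and Iglc1 and Iglc2 were at 848 ± 65.9 and 760 ± 27.8 TPM. The V segments gave lambda a much smaller part, with summed TPM of 2150 ± 78.5 for kappa and 206.2 ± 3.485 for lambda V segments. The constant region share is thus not a measure of the share of kappa cells. The highest kappa V segment was Igkv1-110 at 128 ± 8.65 TPM and the highest lambda V segment Iglv1 at 82.6 ± 2.70 TPM.

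Genes of antigen presentation and signalling were at high levels. The MHC class II list had a median of 217 ± 18.1 TPM, with the invariant chain gene Cd74 at 5769 ± 233 and H2-Ab1 at 1783 ± 90.4 TPM. The B cell receptor signalling list had a median of 102 ± 6.28 TPM, led by the kinase gene Syk at 308 ± 16.7 TPM. Members of the immediate early list, genes induced within minutes by many stimuli, were also abundant, with Fosb at 892 ± 119, Jund at 769 ± 63.9 and Fos at 715 ± 109 TPM. NF-kappaB target genes had a median of 75.8 ± 4.55 TPM, led by Tnfaip3 at 252 ± 30.2 TPM, and survival receptor genes a median of 62.4 ± 3.39 TPM, with Tnfrsf13c, the BAFF receptor, at 105 ± 3.12 TPM. The proliferation list had a median of 2.18 ± 0.231 TPM. Xist, which is expressed from the inactive X chromosome, was at 103 ± 9.81 TPM. In the gene table, counts of Uty, Kdm5d, Ddx3y and Eif2s3y, on the Y chromosome, lay between 0 and 4 in every library. The other quantifier gave 22 to 45, 161 to 215, 10 to 21 and 0 to 3 counts for these genes.

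Interferon-stimulated genes fell together at 62 days relative to 55 days. All 19 tested members were lower at 62 days, with a median log2 fold change of -0.81 (camera adjusted p = 8.76e-14; adjusted p = 0.837 with an estimated correlation). In 19 of 19 both 55-day libraries stood above both 62-day libraries, which chance gives for 16.7% of single genes. The members are not independent (estimated correlation 0.577), so 1 shared order of the libraries would give this count. Over all genes 2 members passed the edgeR test, and 15 passed when adjusted over the list alone. Ifit3, an antiviral protein that binds RNA, fell by 1.44 on the log2 scale (SE 0.21, edgeR adjusted p = 0.0217), from 14.3 ± 2.29 CPM at 55 days to 5.24 ± 1.56 CPM at 62 days (SD, n = 2). Zbp1, a sensor of nucleic acids, fell by 0.84 (SE 0.13, edgeR adjusted p = 0.031). With alike folds both missed the threshold in the other quantifier (edgeR adjusted p = 0.136 and 0.149), with no count filter (0.0533 and 0.0739) and with a mean count of at least 50 (0.0713 and 0.0797). Passing over the list alone were also Irf7 with a log2 fold change of -0.79 (SE 0.15), Mx1 with -0.73 (SE 0.15) and Stat1 with -0.36 (SE 0.07). The summed TPM of macrophage and monocyte markers was 43.6 and 34.8 in the 62-day libraries and 58.1 and 40.1 in the 55-day libraries, so the ages overlapped. The sum of T cell markers did not overlap, at 11.6 and 15.4 TPM against 21.3 and 17.8 TPM, nor did that of all non-B markers without Pecam1, Itgb3 and Lck, at 81.7 and 93.0 TPM against 104 and 101 TPM.

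Heat shock genes fell as well. All 11 tested members were lower at 62 days, with a median log2 fold change of -0.30 (camera adjusted p = 3.07e-06; adjusted p = 0.837 with an estimated correlation). Over all genes 2 members passed, and 7 passed when adjusted over the list alone. Hspa1a, the inducible chaperone of the 70-kDa family, fell by 1.13 on the log2 scale (SE 0.15, edgeR adjusted p = 0.0103). Hsph1, its nucleotide exchange factor, fell by 0.60 (SE 0.07, edgeR adjusted p = 0.00548), from 164 ± 11.8 to 109 ± 2.45 CPM (SD, n = 2). Hspa8 had a log2 fold change of -0.25 (SE 0.07) and Dnaja1 of -0.30 (SE 0.08), both past the threshold over the list alone.

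**Figure D2:**
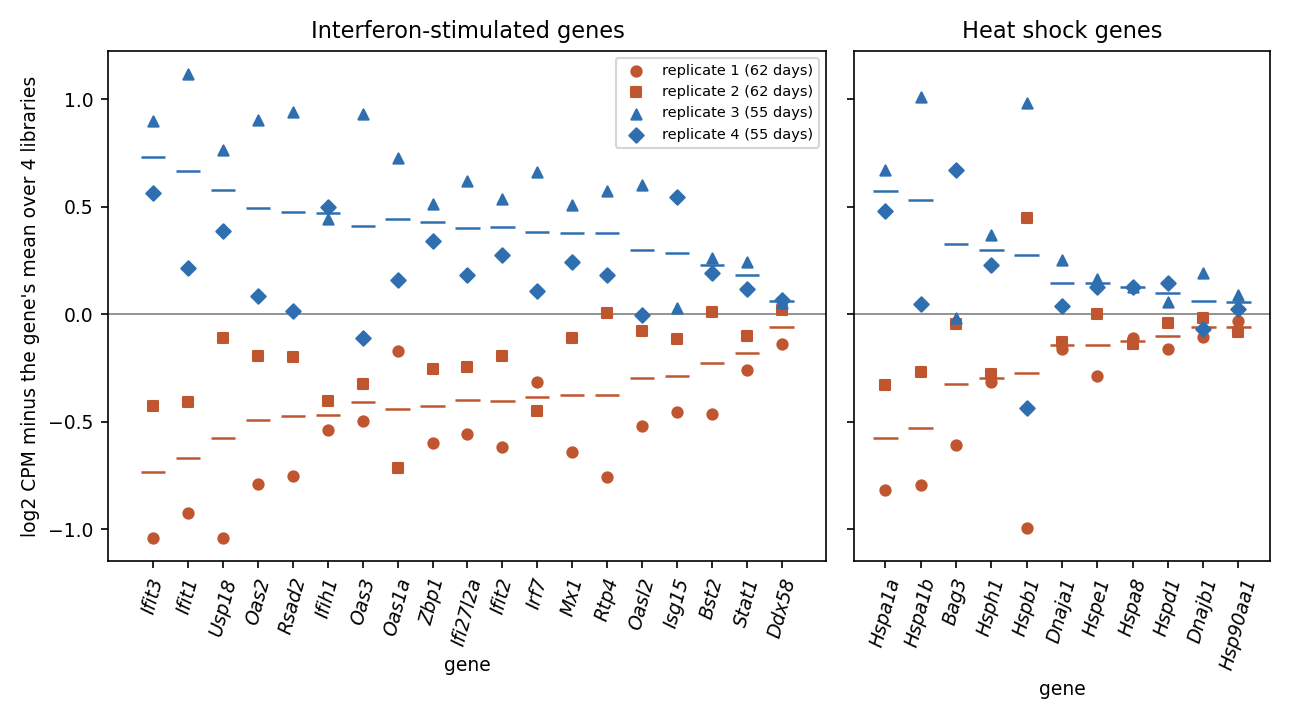
Log2 CPM of each interferon-stimulated gene (left) and heat shock gene (right) minus its mean over the 4 libraries. Points are libraries, orange for 62 days and blue for 55 days, and short bars are means of each age (n = 2). For Ifit3 the 62-day libraries were at 4.14 and 6.34 CPM and the 55-day libraries at 15.9 and 12.6 CPM.

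Immediate early genes were slightly lower at 62 days in 15 of 17 tested members, with a median log2 fold change of -0.16 (camera adjusted p = 0.000773; adjusted p = 0.837 with an estimated correlation). No member passed over all genes (0 of 17), and 7 passed when adjusted over the list alone, among them Fos with a log2 fold change of -0.32 (SE 0.09), Dusp1 with -0.27 (SE 0.07) and Ier2 with -0.27 (SE 0.07). This call depended on replicate 1, since the camera adjusted p was 0.279 without it.

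Markers of macrophages and of T cells were also lower at 62 days, from low levels. Of 12 macrophage and monocyte genes 10 were lower, with a median log2 fold change of -0.50 (camera adjusted p = 0.00814; adjusted p = 0.837 with an estimated correlation), and 0 members passed over all genes or when adjusted over the list alone. Csf1r, the receptor of a macrophage growth factor, had a log2 fold change of -0.52 (SE 0.16) and C1qc, a complement component, of -0.79 (SE 0.28), whereas Hmox1 had 0.38 (SE 0.18) and Spic 0.42 (SE 0.22). All 6 tested T cell genes were lower, with a median log2 fold change of -0.46 (camera adjusted p = 0.00814; adjusted p = 0.837 with an estimated correlation), and 0 passed singly by either count, the count adjusted over the list alone included. The camera adjusted p of the macrophage list was 0.222 without replicate 2 and 0.475 without replicate 3, where the median was -0.20. For the T cell list it was 0.187 without replicate 1 and 0.146 without replicate 3.

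Replication-dependent histone genes were lower at 62 days in 43 of 63 tested members, with a median log2 fold change of -0.14 (camera adjusted p = 0.00863; adjusted p = 0.837 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The camera adjusted p was 0.222 without replicate 2 and 0.453 without replicate 4. Mitochondrially encoded mRNAs were the list that was higher at 62 days, in 12 of 13 members, with a median log2 fold change of 0.27 (camera adjusted p = 0.0038; adjusted p = 0.837 with an estimated correlation). Over all genes and adjusted over the list alone 1 member passed, mt-Nd4l. In replicate 4 mt-Nd1 was at 71.2%, mt-Nd5 at 63.1% and mt-Cytb at 72.7% of the mean of the other libraries, but mt-Nd6 was at 104%, and mt-Co2, which shares reads with a nuclear copy, at 1020%. For mt-Nd4l, summed with the nuclear copy Gm10222 that shares its reads, CPM was 148, 140, 148 and 97.0 in replicates 1 to 4, so that replicate 4 alone was low, and the other quantifier gave a log2 fold change of -0.04. The camera adjusted p was 0.314 without replicate 4 and 0.265 without replicate 1.

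The other 33 lists did not pass, with camera adjusted p from 0.0895 for kappa V segments to 0.993 for plasma cell genes. The pan-B list had a median log2 fold change of 0.07, the follicular list -0.01, the marginal zone list 0.03, the MHC class II list -0.02 and the B cell receptor signalling list 0.01. Rag1, a recombinase of developing lymphocytes, had a log2 fold change of 1.71 (SE 0.29, edgeR adjusted p = 0.0632) and Igha of -1.63 (SE 0.28, edgeR adjusted p = 0.0632). Both missed the threshold over all genes.

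Of 14127 genes tested one by one, 19 differed between the ages, 7 higher and 12 lower at 62 days, and 774 had an unadjusted p under 0.05, or 5.48% of the genes against the 5% that chance gives. Appl1, an adaptor of endosomes and insulin signalling, rose by 1.10 on the log2 scale (SE 0.09, edgeR adjusted p = 0.00027), from 31.4 ± 3.61 CPM at 55 days to 67.1 ± 0.833 CPM at 62 days (SD, n = 2). Slc15a2, a transporter of small peptides, fell by 2.06 (SE 0.23, edgeR adjusted p = 0.00424), from 26.6 ± 9.95 to 6.36 ± 0.106 CPM. Il17rd and Klhl41 lay under the mean TPM of 1 that the naming rule asks for and were chosen after their values were seen. Il17rd, a receptor protein that dampens growth factor signals, was at 6.95 and 6.94 CPM in the 62-day libraries and at 0.381 and 0.269 CPM in the 55-day libraries (edgeR adjusted p = 0.00027). Klhl41, a protein of skeletal muscle, had 131 counts at 62 days against 3 at 55 days (edgeR adjusted p = 0.00115), a ratio of 45.2 with a 95% exact counting interval of 15.1 to 222 that holds for the gene table alone. Il17rd lies on chromosome 14 from 27038941 to 27107286 and Appl1 beside it from 26918988 to 26971232 (mm10). Klhl41 lies on chromosome 2 from 69670120 to 69684230, and Slc15a2 on chromosome 16 from 36750177 to 36784962. Each of these 4 genes kept its direction in the other quantifier and passed there too, with adjusted p in edgeR of 0.0188 or less. The sizes differed there for Klhl41, with a log2 fold change of 1.84 and 37.2 and 40.4 counts at 55 days, against 5.38 in the gene table, and for Il17rd, with 3.25 against 4.39. They were alike for Appl1, with 1.05, and Slc15a2, with -2.10.

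**Figure D3:**
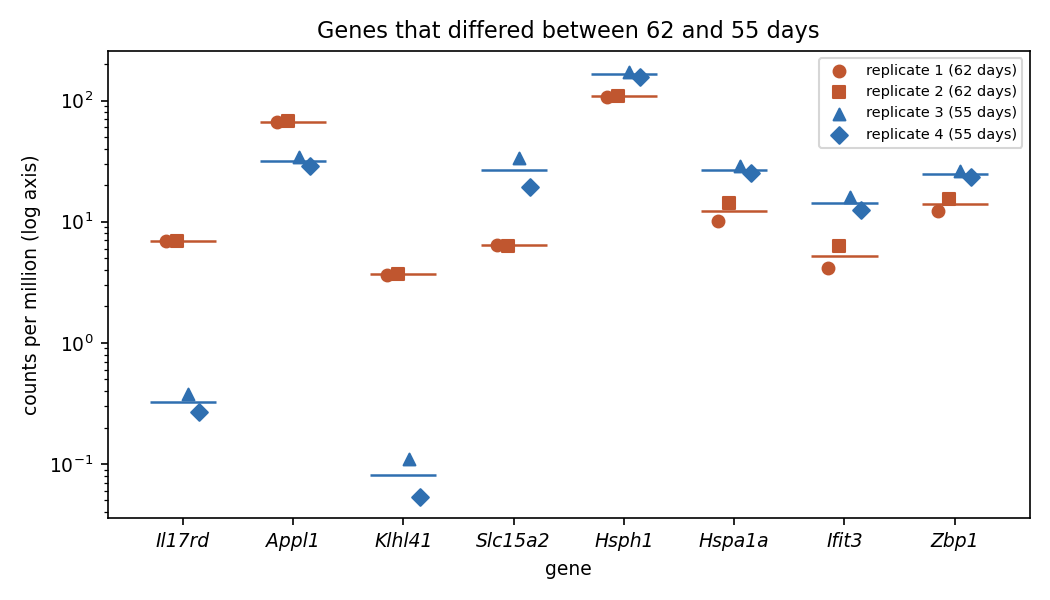
CPM (log axis) of 8 genes that differed between the ages, with 1 point per library and a bar at the mean of each age (n = 2). Orange marks 62 days and blue 55 days. Il17rd, Appl1 and Klhl41 lie higher at 62 days and the other 5 genes lower, as for Slc15a2 with means of 6.36 and 26.6 CPM.

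Several other calls lay on genes whose reads are shared with near copies, and 11 of the 19 genes had high assignment uncertainty. One of the 2 entries named Chtf8 (ENSMUSG00000117748) had a log2 fold change of -4.18 (SE 0.31), but the sum of both overlapping entries differed by -0.05. Rps12, a ribosomal protein gene, had -0.61 (SE 0.07), and its sum with Rps12l1 and Gm10163 differed by -0.10. The mitochondrial gene mt-Nd4l had 0.58 (SE 0.07), and its sum with Gm10222 differed by 0.23, a value that rests on replicate 4. The pseudogenes Gm12918, Gpx4-ps2 and Gm15429 and the small nuclear RNA gene Gm26244 were also called. Gm12918, Gpx4-ps2 and Gm26244 had 0 counts in the other quantifier in every library. The assignment uncertainty of Gm26244 in the 62-day libraries, 68.3 and 34.3 reads, was of the same order as its 67 and 47 counts at 55 days, so no fold is given. Gm15429 was at -1.03 in the other quantifier (edgeR adjusted p = 0.989), and its call was lost without replicate 4 (edgeR adjusted p = 0.105). The remaining calls, Gm14288, Gm5537, Gm14440 and Amy2a5, were under a mean TPM of 1 and were also picked after their values were seen. Gm14288, Gm5537 and Gm14440 had an assignment uncertainty above 10 reads in every library, including those with no counts, so no fold is given for them. Amy2a5, a pancreatic amylase gene, had a log2 fold change of -4.12 (SE 0.65, edgeR adjusted p = 0.0429), and -2.15 in the other quantifier, where its call was lost (edgeR adjusted p = 0.565).

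**Figure D4:**
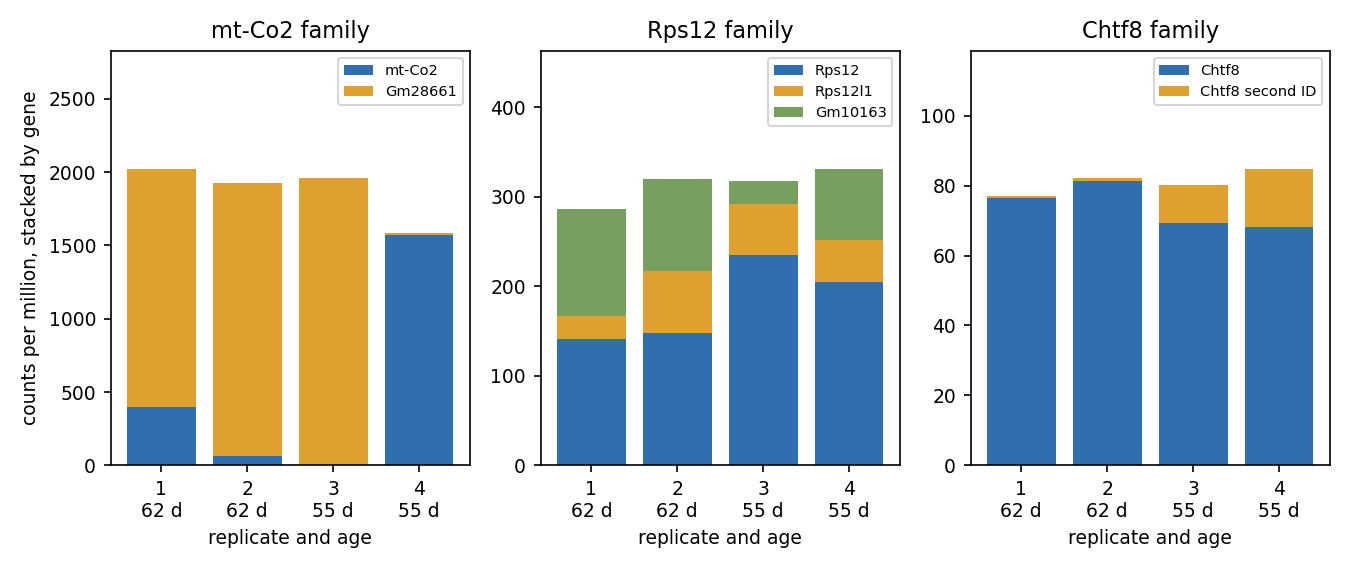
CPM of genes that share reads, stacked by gene, for each library (replicate number and age in days). In the mt-Co2 panel the split between mt-Co2 and its nuclear copy Gm28661 differs between libraries, with 6983, 1173, 2 and 29501 counts on mt-Co2, while the sums are 35323, 35050, 35999 and 29756.

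The number of genes called depended on the libraries used and on the processing, and why was not tested. It rose whichever library was left out. With all libraries it was 95 with spike-in scaling and 2 by limma on log2(TPM + 1). Age cannot be told apart from harvest day or litter with 2 mice per age, and if the free-text label of 62 days for all 4 libraries is right, none of these differences is one of age.

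Small structural RNAs dominated the TPM of these ribosome-depleted libraries, but not the counts. The 2 copies of the signal recognition particle RNA, Rn7s1 and Rn7s2, were each at 144800 ± 4436 TPM (SD, n = 4) with identical values, and Rn7sk, which restrains transcription elongation, was at 68460 ± 1626 TPM. Next came Gm26917 at 31370 ± 2413, the RNA subunit of ribonuclease P, Rpph1, at 15540 ± 869 and that of a related ribonuclease, Rmrp, at 10380 ± 254 TPM. The spliceosomal RNA genes Gm24265, Gm23472, Gm23444, Gm24407, Gm23849, Gm24950, Gm23971, Rnu2-10 and Gm22513 lay between 3023 ± 278 and 9523 ± 912 TPM. Gm23472 and Gm23444 had identical values, as did Gm23849, Gm24950, Gm23971 and Rnu2-10, so these are not separate measurements. TPM is corrected for length, which raises short RNAs. Small nuclear RNA genes as a class took 8.24% of TPM but 0.636% of counts. Gm42418 was at 8390 ± 424 TPM, and the long noncoding RNA Malat1 at 6143 ± 296 TPM. Besides Cd74, the protein-coding genes among the top 20 were Rps27 at 3255 ± 245 and the elongation factor gene Eef1a1 at 2827 ± 103 TPM. By counts, nuclear protein-coding genes outside the ribosomal protein and immunoglobulin classes took 64.5% ± 0.650. Genes that the annotation classes as long intergenic RNAs took 12.5% ± 0.754. Most of this share lay on Gm26917, Malat1 and Gm42418, with mean CPM of 84770, 19790 and 15320. Gm26917 and Gm42418 lie side by side on chromosome 17, and what RNA their reads came from was not tested. The class of Rn7s1 and Rn7sk took 7.79% ± 0.466 and mitochondrial ribosomal RNA 6.43% ± 0.487. Ribosomal protein mRNAs took 2.52% ± 0.0213, mitochondrial mRNAs 1.04% ± 0.119 and immunoglobulin genes 0.799% ± 0.0214 of counts. The ribosomal protein class was drawn by symbol (Rpl or Rps and a number). It therefore includes kinase genes such as Rps6ka1 and leaves out Rplp0 and Rpsa. At a TPM of at least 1 in every library 11387 genes were detected, 9627 of them protein-coding.

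The genes on which the quantifiers differed were of several classes. Across 55450 genes, which are not independent replicates, Spearman coefficients between them were 0.848 to 0.855 in the 4 libraries. The levels of 369 genes differed at least 4-fold in the same direction in every library, of which 215 were higher in the gene table. Of these 215 genes 75 were small nucleolar RNAs, 66 processed pseudogenes and 35 small nuclear RNAs. The largest ratios were those of Rmrp, Gm24265, Gm24407, Gm23444, Gm23472, Gm24950, Gm23971, Gm23849, Rnu2-10 and Gm22513, all under 1 TPM in the other table. The 154 genes higher in the other table included 32 protein-coding genes, 30 long intergenic RNAs, 28 genes of the TEC class (to be experimentally tested) and 28 processed pseudogenes. They were led by Gm19220, with 3297 ± 356 TPM there and 0 in the gene table, and by Gm47283, on the Y chromosome of the annotation, with 341 ± 103 TPM there and 0 in the gene table. Next were Gm42860, Gm47673, Gm38356, Gm48765, Gm49274, Gm26905, Gm43590 and Gm44427, between 39.5 ± 9.84 and 104 ± 23.4 TPM in the other table. Which table was higher for more genes depended on the setting. With a mean TPM of at least 1 it was 364 genes higher in the gene table against 1230 in the other, 1594 in all, by counts 119 against 202, and at 2-fold 243 against 253.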

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

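No explanation was tested for the values in this part. Among 104 profile values with 1 value per library, 6 had a library far from the other 3 by Dixon's ratio; chance gives about 1 in 20, and the values overlap. Replicate 4 was the outlying library in 5 of the 6. The immature B cell list had a median of 1.46 TPM in replicate 4 and 0.79 to 0.875 TPM in the others. The erythroid list had a median of 1.55 TPM there and 0.56 to 0.725 TPM in the others. Its summed TPM did not set replicate 4 apart, at 9.22, 29.57, 11.55 and 30.13 in replicates 1 to 4. Rps27, a ribosomal protein gene, was at 2888 TPM there and at 3363 to 3396 TPM in the others. Genes of the remaining minor RNA classes took 0.205% of counts there and 0.191% to 0.193% in the others. Ighe, the IgE constant region, took 0.00134% of heavy chain constant region TPM there and 0 in the others. With 0 in all others any value above 0 is flagged by Dixon's ratio, so the Ighe flag says little about replicate 4. Natural killer markers summed to 9.17 TPM in replicate 1 and to 8.58 to 8.64 TPM in the others.

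Reads were also seen outside the comparisons. The phiX entry, the genome of a sequencing control, held between 42 and 48 reads per library, above the 3 counts that a count of 0 allows. The 26248 entries with numeric identifiers, which no file names, together held between 4 and 18 reads per library. The limit of 3 counts is for a single entry, so this sum cannot be set against it.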

How the results depend on the processing

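The test of genes of low assignment uncertainty was chosen after seeing the data. For 19 genes differing between ages (7 higher and 12 lower at 62 days), DESeq2 size factors, library size, limma-voom, no filter, and leaving out immunoglobulin or mitochondrial genes gave 14 to 23. Spike-in scaling gave 95 (31 and 64), the DESeq2 Wald test 37 (16 and 21), protein-coding genes only 42 (17 and 25) and genes of low assignment uncertainty 31 (11 and 20). An adjusted p of 0.10 gave 31, with 13 higher. A mean count of at least 50 gave 9 (4 and 5), the other quantifier 8 (4 and 4), limma on log2(TPM + 0.1) 3 (0 and 3) and on log2(TPM + 1) 2 (0 and 2). Leaving out each replicate gave 81 to 199 (26 to 106 higher and 55 to 93 lower); an age with 1 library was then assumed to vary like the other. The cause was not tested, except that fewer genes were tested with the stricter filters. Of the 19 genes, all were also called with spike-in scaling and 6 with the other quantifier.

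All 7 lists that passed failed with an estimated correlation (0 passed, adjusted p 0.837 for each) and by fry (0 passed; adjusted p 0.549 for interferon-stimulated, heat shock and T cell genes, 0.758 for immediate early, macrophage and histone genes, 0.802 for mitochondrial genes). All 7 passed with DESeq2 size factors and spike-in scaling. Leaving out each replicate, the camera adjusted p ranged from 2.3e-15 to 3.37e-06 for interferon-stimulated genes, 9.87e-06 to 0.00643 for heat shock, 6.32e-05 to 0.279 for immediate early, 0.000269 to 0.314 for mitochondrial, 0.000682 to 0.475 for macrophage, 0.00187 to 0.187 for T cell and 0.000275 to 0.453 for histone genes. Among named genes 1 value reversed: mt-Nd4l was at -0.04 in the other quantifier.

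CPM in place of TPM moved the pan-B median to 576, the non-B share from 0.0198% of TPM to 0.0460% and the kappa share to 62.7%. The other quantifier moved them to 326.7 TPM, 0.0260% and 61.6%, and the spike-in share to 0.237%. By TPM the spike-in share was 0.366% and the nuclear protein-coding share 28.9%. With a mean TPM of at least 1, 1594 genes differed between quantifiers. CPM is not length-corrected and TPM is; the cause of the other shifts was not tested. Of the alternatives for named genes, the medians of other marker lists, isotypes and RNA classes, 356 stayed alike, 38 lost the call of a named gene and 39 moved. Depth limits genes near 3 counts.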

Other observations

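The tests of the interferon, single-gene and pancreas patterns below were chosen after the results were seen. Some gene groups have not been described above. Circadian clock genes had a median of 8.44 ± 0.621 TPM (SD, n = 4), with the period gene Per1 at 274 ± 16.8 and Ciart at 73.8 ± 5.93 TPM. Glucocorticoid response genes were led by Tsc22d3 at 581 ± 20.7 TPM, and homing genes included S1pr1 at 99.0 ± 5.30 TPM. Genes of the unfolded protein response had a median of 70.8 ± 4.20 TPM, led by the chaperone gene Hspa5 at 271 ± 27.3 TPM. Among genes of Toll-like receptor signalling Unc93b1 was at 195 ± 10.4 and Cd180 at 159 ± 10.6 TPM. Cholesterol synthesis genes had a median of 6.61 ± 1.23 TPM, hypoxia and glycolysis genes 11.4 ± 1.08 TPM and p53 target genes 4.30 ± 0.355 TPM. The X-linked list had a median of 51.3 ± 4.90 TPM, ribosomal protein genes (drawn by symbol, some kinase genes included) 472 ± 20.2 TPM and replication-dependent histone genes 23.8 ± 1.69 TPM.

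Interferon-stimulated genes were lower at 62 than at 55 days. RNA of macrophages and monocytes as the whole source is argued against only weakly. Such cells would bring their own abundant transcripts. The rise of their mean summed marker TPM at 55 days was 9.79% of the rise in the interferon-stimulated genes. It was 18.4%, 4.41%, 1.28% and 13.8% without replicates 1 to 4 in turn. This share leans on Ifi27l2a, the interferon-stimulated gene of highest mean TPM (78.7). The median log2 fold change of the markers, -0.50, was not far from the -0.81 of the interferon-stimulated genes. The marker sum was lower in replicate 4 of 55 days, at 40.1 TPM, than in replicate 1 of 62 days, at 43.6 TPM. Csf1r was at 15.6 and 12.1 CPM at 62 days and at 22.8 and 16.8 CPM at 55 days, and Lyz2 at 3.45 and 2.79 against 4.08 and 3.44 CPM. The direction did not come from replicate 3 alone, since replicate 4 was also above both 62-day libraries in 19 of 19 genes. The median log2 fold change was -0.57 without replicate 3 and -0.93 without replicate 4. The members move together (estimated correlation 0.577), so 1 shared order of the libraries would give the 19 of 19, and chance was not excluded. With all libraries the camera adjusted p was 0.837 with an estimated correlation. A difference in interferon exposure with age, or with harvest day or litter, or RNA of T cells or other cells may underlie the pattern and was not tested. Mean summed TPM of T cell markers was 13.5 at 62 days and 19.55 at 55 days, against 195.8 and 296.3 for the interferon-stimulated genes. The sums of natural killer markers, 8.905 and 8.605 TPM, and of neutrophil markers, 7.96 and 6.85 TPM, were lower at 55 days. Those of the remaining non-B lists were higher at 55 days.

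Il17rd, Klhl41 and Slc15a2 differed severalfold between the ages. Reads shared between gene copies as the whole source are argued against, since in the other quantifier all 3 kept their direction and the smallest absolute log2 fold change was 1.84, that of Klhl41, although its size was 5.38 in the gene table. A local difference at each locus, carried by only some of the mice, could not be told apart from a change in single genes. A variant that merely separates the parent strains is no such difference, since every mouse of this first-generation cross carries both genomes. Of 24 neighbours within 500 kb, genes already called left out, 3 had an unadjusted p under 0.05 against 1.31 by chance (one-sided exact binomial p = 0.142). With Appl1 among the neighbours, as first run, the test gave 4 of 25 and a one-sided exact binomial p of 0.0453. Appl1, a neighbour of Il17rd that was already called, was then left out because it had been seen to differ. Leaving it out also removes what a local difference at Il17rd would show. Neither p value therefore decides between a local difference and a change in single genes. Age, harvest day and litter stay open, untested.

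Amy2a5 and Ctrb1, genes of the exocrine pancreas, were higher at 55 days, Ctrb1 with a log2 fold change of -3.58 (SE 0.81, edgeR adjusted p = 0.22). Trace pancreas RNA in the 55-day libraries is a candidate source, since the pancreas lies beside the spleen. On a list of 19 other acinar genes, of which 1, Ctrl, had a mean TPM above 1, the summed counts were 16 and 44 at 62 days and 183 and 123 at 55 days, a ratio of 2.80 between the nearest libraries. All 17 genes with at least 3 counts were higher at 55 days (two-sided exact binomial p = 1.53e-05, with genes not independent). The most abundant list gene reached 26 counts in a library. Whether acinar cells or their free RNA passed the purification by CD19 was not tested. Shared reads are argued against for the list, since over its 16 genes of low assignment uncertainty the ratio was 2.85, but stay open for Amy2a5, which was at -2.15 in the other quantifier with its call lost (edgeR adjusted p = 0.565); reads from a library sequenced alongside stay open, untested.

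The 4 libraries can be split 2 against 2 in 3 ways, too few for a share under 0.05. The split by age called 19 genes and the higher of the others 3. The other quantifier placed 161 to 215 counts per library on Kdm5d and 22 to 45 on Uty, both on the Y chromosome, where the gene table had 0 to 2 and 1 to 4. The split of mitochondrial reads between genes and nuclear copies also differed between libraries: mt-Co3 held 15029, 2484, 11901 and 1953 counts and its copy Gm28437 14107, 26980, 17726 and 22929, with sums of 29136, 29464, 29627 and 24882.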
